A study of Rattus norvegicus with 6 samples.

How the data were processed

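RNA-seq of neonatal rat cardiomyocytes was analysed from a table of the whole series, with 3 libraries of cells given DMSO and 3 of cells given 3Cl-HBA at 40 µM for 48 h, per the labels. RNA was prepared with a KAPA RiboErase kit, which removes ribosomal RNA, and sequenced on an Illumina instrument, per the labels' protocols. The labels' protocols name DESeq2 as the authors' tool. The aligner, the counting program, its strand setting, the genome build and the annotation release are not given in the sources used here, so reads of a gene and of a gene overlapping it on the other strand cannot be told apart. Coordinates are printed as the deposited table gives them. The deposited table gives for each of 22250 rat genes with Ensembl identifiers whole-number read counts per library, not normalised, per the file headers. It also gives FPKM, which per the file headers the authors computed; the FPKM equal the count divided by gene length and by the library's total of counts, within a relative gap of 8.2e-08. Gene length in bases is the authors' value, per the file headers, and was used to look for length trends. The FPKM were not tested. No row lacked a gene identifier, and 317 rows share their gene name with another row.

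The columns were assigned to treatments through the treatment protocol in the labels and to replicate numbers through the number in the column name and in the library's title. Library totals were 13240800 to 17202191 reads. Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr by group with a minimum count of 10, robust glmQLFit, glmQLFTest, no block), which kept 13903 genes. The median biological coefficient of variation was 0.0646. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and log2 fold changes are 3Cl-HBA minus DMSO. SEs were the absolute log2 fold change, without shrinkage, divided by the square root of the F statistic, and 95% intervals used the test's degrees of freedom. Printed CPM use TMM-scaled totals. Intervals rest on the spread between these 3 libraries per group, with each gene's variance drawn toward that of other genes. An exact permutation test of 3 against 3 cannot give a p under 0.1 and was not used. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were alternatives, and an adjusted p that DESeq2 gave as NA, as for 4143 genes, stayed NA.

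Genes were named by a rule fixed before the data were examined. It names Hcar1, Nppa, Nppb, Myh6, Myh7 and Acta1 always, the called genes with the largest fold changes, up to 3 called members of each list, and, where fewer than 10 genes pass in a direction, the 5 genes with the smallest unadjusted p among those with a symbol, a mean of at least 5 CPM and groups that do not overlap. Most other genes named as examples of a list are among its 3 most abundant tested members, a rule added after the data were seen, and Slc16a1, Hcar2, Rps6 and genes given with an unadjusted p under 0.05 were chosen after their values were seen. The 31 lists were also fixed before the data were examined. They cover lactate handling and hydroxycarboxylic acid receptors, fetal and hypertrophy genes, sarcomere, calcium handling and excitability, fatty acid uptake and oxidation, lipolysis and lipid droplets, glycolysis and glucose uptake, nuclear oxidative phosphorylation, mitochondrially encoded genes, cAMP-responsive and immediate early genes, DNA replication and mitosis, p53 targets and apoptosis, ER stress and amino acid response, cholesterol and fatty acid synthesis, hypoxia response, oxidative stress response, aryl hydrocarbon receptor targets, inflammation and chemokines, interferon response, autophagy and lysosome, extracellular matrix and matrix remodelling, histone and ribosomal protein RNA, adenylyl cyclase, phosphodiesterase and Gi signalling, natriuretic, renin-angiotensin and endothelin signalling, circadian clock, and markers of fibroblasts, smooth muscle and pericytes, endothelium, macrophages and leukocytes, Schwann cells and neurons, and erythroid cells. Of 604 listed symbols, 590 were matched, 16 of them through a RefSeq table of assembly GRCr8 used for names only. Titin was not analysed here, and single values of some list members are not reported here.

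Lists with at least 5 tested members were tested on log2 CPM (prior count 2) with camera at a preset inter-gene correlation of 0.01, again with the correlation estimated, which leaves camera 4 degrees of freedom in place of 13901, and with fry, each adjusted over the 30 lists. The erythroid list, with 4 tested members, was below that minimum. A list's mean log2 difference and its 95% interval come from limma on the mean log2 CPM of its members in each library. There each list's variance was drawn toward that of the other lists, so an interval can be narrower or wider than the list's own spread gives. Annotation terms were those the deposited table pairs with genes. The procedure was tested on simulated counts drawn from the real means, spread and depths of this comparison over 13903 genes. With many genes changed at once, it recovered 90% of 2-fold and 77% of 1.5-fold changes with 7.63% false calls. Responses of a few genes, for which the adjusted p is harder to pass, were not simulated. The procedure called the 1 list that was shifted, by 0.3 on the log2 scale, and 0 others. Genes were drawn independently, without the correlation between genes of real lists, so the 0 does not measure false list calls here. Smaller list shifts were not simulated. Alternatives were other scalings, no filter or a filter of at least 5 CPM in 3 libraries, DESeq2, limma-voom, the replicate number as a block, and each library left out in turn. Added after the data were seen were removal of each library's length trend, the estimated inter-gene correlation as an alternative, prior counts of 0.5 and 5 in the list tests, and camera over terms. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.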

Results

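RNA was measured in neonatal rat cardiomyocytes, heart muscle cells freed by enzyme digestion from the hearts of newborn Sprague-Dawley rats and kept in culture. The cells were given either the solvent DMSO or the compound 3Cl-HBA at 40 µM for 48 h, and each treatment had 3 libraries. The DMSO libraries held 13942979, 14499065 and 13240800 reads assigned to genes, and the 3Cl-HBA libraries held 14607337, 17202191 and 15732803, so each treated library was deeper than each DMSO library. Between 16460 and 16671 of the 22250 genes in the table had at least 1 read in a library. The 13 mitochondrially encoded genes took 6.96%, 7.03% and 6.87% of the reads in DMSO and 6.83%, 7.71% and 7.21% after 3Cl-HBA, and Mt-co1, a subunit of cytochrome c oxidase, was the most abundant transcript in each library. The labels number the libraries 1 to 3 within each treatment and do not say that they came from separate cultures or animals. The p-values therefore speak only for these samples, whose spread may be technical. With camera at a preset correlation, a list's genes are compared with other genes, so those p-values do not measure the spread between libraries. Levels are given as read counts per 1000000 reads (CPM), as means ± SD of the 3 libraries of a group.

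The cultures expressed heart muscle genes at high levels together with genes of other heart cells, at similar levels in both groups. The myosin heavy chain Myh6 had 8457 ± 352 CPM in DMSO and 8429 ± 255 CPM after 3Cl-HBA, cardiac actin Actc1 had 4963 ± 143 and 5061 ± 184 CPM, and the calcium pump Atp2a2 had 4598 ± 111 and 4487 ± 90.1 CPM. Collagen transcripts were also abundant, with Col1a1 at 10450 ± 436 and 10171 ± 96.4 CPM and Col3a1 at 3159 ± 49 and 3146 ± 35 CPM. Among markers of other cell types, the smooth muscle actin Acta2 had 968 ± 59.5 and 978 ± 14.9 CPM, the endothelial receptor Eng 411 ± 31.5 and 412 ± 12.2 CPM, the macrophage lysozyme Lyz2 182 ± 10.6 and 188 ± 4.01 CPM, and the neuronal hydrolase Uchl1 59.3 ± 0.76 and 63.3 ± 6.25 CPM. Acta2 and Uchl1 are also on the list of fetal and hypertrophy genes, so their levels do not by themselves show smooth muscle cells or neurons. No member of the fibroblast, smooth muscle and pericyte, endothelial, macrophage and leukocyte, or Schwann cell and neuronal lists passed the test, of 18, 13, 13, 16 and 7 tested. The mean log2 differences of these lists, 3Cl-HBA minus DMSO, were 0.0052 (95% interval -0.053 to 0.063), -0.022 (-0.093 to 0.049), -0.031 (-0.155 to 0.092), 0.014 (-0.070 to 0.099) and 0.089 (-0.040 to 0.217) in that order. The median log2 fold change of the Schwann cell and neuronal list, 0.0857, turned to -0.0113 without 3Cl-HBA replicate 1. It was -0.0531 with no filter on low counts and -0.0554 with DESeq2.

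No single transcript passed the test for a difference between 3Cl-HBA and DMSO. Of 13903 genes tested with edgeR's quasi-likelihood test, 0 had a Benjamini-Hochberg adjusted p under 0.05, and therefore 0 passed with at least a 2-fold change. The smallest adjusted p was 0.845. At an unadjusted p under 0.05 there were 711 genes, 351 higher and 360 lower, which is 5.11% of those tested, where chance alone gives 695. DESeq2 also called 0 genes, with 405 at an unadjusted p under 0.05 and a smallest adjusted p of 0.544. It was run without the filter on low counts, so the 405 come from a larger set of genes than the 711 and are fewer than chance gives. The 3 treated libraries lay entirely above or entirely below the 3 DMSO libraries in 1453 genes, or 10.5%, where chance gives 10%. The median absolute log2 fold change was 0.069, and 0.057 for the 11110 genes with a mean of at least 5 CPM. Without DMSO replicate 2 or 3, or without 3Cl-HBA replicate 2 or 3, the count of genes past the threshold became 1, 8, 2 and 3, of which 0, 2, 2 and 0 changed at least 2-fold. With no filter on low counts it became 2, Kmt2a and Myh9l1, named here after their values were seen.

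The data limited how large an undetected difference could be for most genes. The 95% interval of the fold change lay inside 2-fold for 12832 genes (92.3%) and inside 1.5-fold for 11243 genes (80.9%). Among genes with a mean of at least 5 CPM these shares were 99.8% and 97.5%. In simulated libraries with the same depths and spread, the test recovered 450 of 500 added 2-fold changes (90%) and 385 of 500 added 1.5-fold changes (77%). Both kinds of change were added together, to many genes per simulation, which eases the adjusted threshold. Recovery of a change in only a few genes was not simulated. Libraries differed from each other about as much within a group as between groups. The SD of log2 CPM ratios over genes was 0.156 to 0.193 for the 6 pairs of libraries within a group and 0.160 to 0.195 for the 9 pairs between groups, with a median of 0.175 for both. In a chi-square comparison of counts, each pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 2.79 to 5.13.

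**Figure D1:**
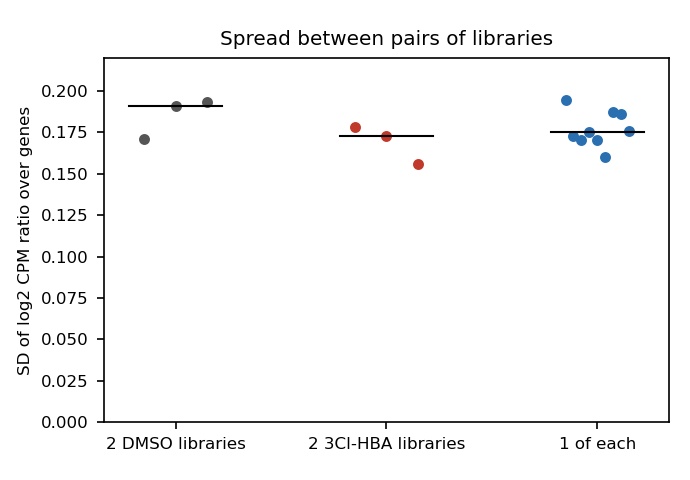
Each point is a pair of libraries and the vertical axis is the SD over genes of the log2 ratio of their CPM; horizontal lines mark medians. Pairs made of 1 library of each treatment spanned 0.160 to 0.195, and pairs within a treatment 0.156 to 0.193.

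The receptor named in the series title was barely detected. Hcar1, a G-protein-coupled receptor for lactate (ENSRNOG00000026661, chromosome 12, 38144855 to 38146271, plus strand, in coordinates of a genome build not given in the sources used here), had 9, 7 and 5 reads in the DMSO libraries and 14, 10 and 5 reads in the 3Cl-HBA libraries. This is 0.501 ± 0.134 and 0.619 ± 0.319 CPM, too low for the gene to enter the test. Fitted without a filter on low counts, its log2 fold change was 0.29 (SE 0.61, 95% interval -0.91 to 1.49, edgeR adjusted p 0.972), so a level 2-fold higher lay within the interval and was not detectable at this depth. The related receptor Hcar2 had 0.094 ± 0.11 and 0.143 ± 0.084 CPM. The other 9 genes of the list of lactate handling and hydroxycarboxylic acid receptors were tested and 0 passed. Of these, 1 had an unadjusted edgeR p under 0.05, and log2 fold changes ran from -0.062 to 0.24. Lactate dehydrogenase Ldha had 1184 ± 28.4 CPM in DMSO and 1167 ± 71.1 CPM after 3Cl-HBA, the lactate transporter Slc16a1 had 329.5 ± 13.7 and 328 ± 0.061 CPM, and its chaperone Bsg had 690.4 ± 20.8 and 691 ± 20.1 CPM. The list's mean log2 difference was 0.010 (95% interval -0.046 to 0.066).

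Natriuretic peptides and other genes that rise in enlarging heart muscle did not pass either. Nppa, which encodes atrial natriuretic peptide (ENSRNOG00000008176, chromosome 5, 164808323 to 164809705), had 3850 ± 160 CPM in DMSO and 3508 ± 294 CPM after 3Cl-HBA, a log2 fold change of -0.13 (SE 0.048, 95% interval -0.232 to -0.037, edgeR unadjusted p 0.0087, adjusted p 0.959). Its lowest treated level was 3176.6 CPM in 3Cl-HBA replicate 2, against 3736.1 and 3611.9 CPM in 3Cl-HBA replicates 1 and 3. Myh7, the slow myosin heavy chain, had 2583 ± 179 and 2414 ± 57.8 CPM (log2 fold change -0.097, SE 0.043, 95% interval -0.185 to -0.0096, edgeR unadjusted p 0.030, adjusted p 0.959). Its highest DMSO level was 2789.5 CPM in replicate 3, against 2485.1 and 2472.9 CPM in DMSO replicates 1 and 2. The intervals and unadjusted p of Nppa and Myh7 do not account for the number of genes tested. Levels of Nppb, the gene of B-type natriuretic peptide, were 385 ± 16.2 and 384 ± 25.6 CPM, and those of skeletal actin Acta1 were 223 ± 12 and 226 ± 11.4 CPM. The signs for Nppb, Acta1 and Myh6, whose log2 fold changes were -0.0039, 0.018 and -0.0048, turned when single libraries were left out. Of 22 tested fetal and hypertrophy genes, 21 sarcomere genes and 23 genes of calcium handling and excitability, 0 passed over all genes. Adjusted over the list alone, 0, 0 and 1 did, the last being Ryr2, the calcium release channel of the sarcoplasmic reticulum, at 968 ± 35.3 and 861 ± 66.4 CPM (log2 fold change -0.17, SE 0.047, adjusted p 0.021 over the list and 0.914 over all genes). Mean log2 differences of these lists were -0.012 (95% interval -0.069 to 0.046), -0.033 (-0.095 to 0.029) and -0.030 (-0.096 to 0.037). The 14 tested genes of natriuretic, renin-angiotensin and endothelin signalling, such as the angiotensin-converting enzyme Ace with 372 ± 10.2 and 357 ± 11 CPM, gave 0 calls and a mean of 0.029 (-0.055 to 0.112). Myh6 and Myh7 are near copies, and each overlaps an unnamed gene on the opposite strand, so reads may be shared between them.

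**Figure D2:**
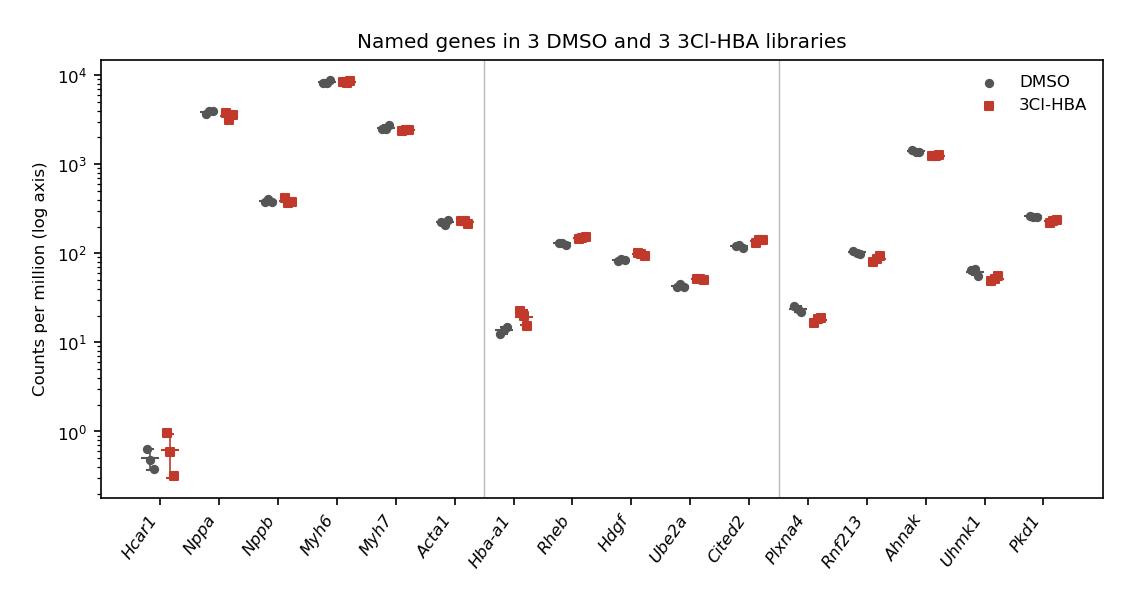
CPM of 16 genes on a log axis, with each library as a point (DMSO circles, 3Cl-HBA squares) and the mean ± SD of 3 libraries as bars. From left to right the panels hold 6 genes fixed in advance, then the 5 higher and 5 lower genes with the smallest unadjusted p. These higher and lower genes had a symbol, a mean of at least 5 CPM and groups that do not overlap. Hcar1, at or below 0.954 CPM in each library, was too low to enter the test, and none of the other genes passed it.

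The 5 genes per direction with the smallest unadjusted p differed by small amounts. They were taken from genes with a symbol, a mean of at least 5 CPM and groups that do not overlap. On the higher side were Hba-a1, an alpha-globin gene, with 13.7 ± 1.36 CPM in DMSO and 19.3 ± 3.62 CPM after 3Cl-HBA (log2 fold change 0.49, SE 0.12, edgeR adjusted p 0.845). Next came Rheb, a GTPase that activates mTORC1 (129 ± 4.04 and 149 ± 2.91 CPM, log2 fold change 0.20), the growth factor gene Hdgf (0.22), the ubiquitin-conjugating enzyme Ube2a (0.25) and the transcriptional co-regulator Cited2 (0.19). On the lower side were the semaphorin co-receptor Plxna4 (23.8 ± 2.05 and 18 ± 1.36 CPM, log2 fold change -0.40), the ubiquitin ligase Rnf213 (-0.24), the scaffold protein Ahnak (1396 ± 37.8 and 1246 ± 34.4 CPM, -0.16), the kinase Uhmk1 (-0.27) and Pkd1, which encodes polycystin-1 (-0.18). SEs of the other genes were 0.042 to 0.101, and none of the 10 passed, with adjusted p of 0.845 or 0.914. Uhmk1 passed without DMSO replicate 3 (adjusted p 0.0382, range 0.0382 to 1 over the alternatives) and Hba-a1 without 3Cl-HBA replicate 3 (0.0469, range 0.0469 to 1). The lower genes have lengths of 3243 to 17602 bases in the deposited table and the higher ones 556 to 1949, and with each library's length trend removed, a setting chosen after the data were seen, Rnf213, Ahnak and Pkd1 moved to -0.156, -0.0695 and -0.105. Hba-a1 is a near copy of Hba-a2 and Pkd1 overlaps Tsc2 on the opposite strand.

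Energy metabolism genes encoded in the nucleus showed no calls. Of the 22 tested genes of glycolysis and glucose uptake, 22 of nuclear oxidative phosphorylation, 23 of fatty acid uptake and oxidation, and 17 of lipolysis and lipid droplets, 0 passed over all genes and 0 adjusted over the list alone. Levels in DMSO and after 3Cl-HBA were 1421 ± 48.5 and 1450 ± 26 CPM for the pyruvate kinase gene Pkm, 2483 ± 57.5 and 2474 ± 146 CPM for the ATP synthase subunit Atp5f1b, 502 ± 10.4 and 508 ± 12.6 CPM for the beta-oxidation enzyme subunit Hadhb, and 463 ± 2.81 and 480.2 ± 15 CPM for lipoprotein lipase Lpl. The mean log2 differences were -0.027 (95% interval -0.093 to 0.039), 0.0064 (-0.072 to 0.084), 0.030 (-0.040 to 0.101) and -0.0079 (-0.098 to 0.082). The medians of the glycolysis and oxidative phosphorylation lists, 0.00014 and 0.00097, turned negative with scaling by library totals alone, as did that of the hypoxia list (0.0016).

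The list of mitochondrially encoded transcripts was higher after 3Cl-HBA by a small amount, a call that rests on a preset correlation. Of 13 members, 12 had a log2 fold change above 0, with a median of 0.071, and the list passed camera, a test of whether a list's genes stand apart from the other genes (adjusted p 0.0029 with a preset correlation, and adjusted p = 0.703 with an estimated correlation). Mt-co1 had 31075 ± 823 CPM in DMSO and 31985 ± 2173 CPM after 3Cl-HBA, and the cytochrome oxidase subunit Mt-co3 9033 ± 63.1 and 9411 ± 81 CPM. No member passed over all genes, and 2 passed adjusted over the list alone, Mt-co2 (log2 fold change 0.11, SE 0.040) and Mt-atp6 (0.13, SE 0.045), both at 0.047. The mean log2 difference was 0.083 with a 95% interval of -0.025 to 0.191 (limma adjusted p 0.585 over the 30 lists). DMSO replicate 1 stood apart. The list's mean log2 CPM was 10.35, 10.5 and 10.525 in DMSO replicates 1 to 3 and 10.477, 10.55 and 10.597 in 3Cl-HBA replicates 1 to 3. The call was lost without DMSO replicate 1 (adjusted p 0.158) and without 3Cl-HBA replicate 2 (0.345, median 0.0316), the library with the highest mitochondrial share, 7.71%, and ranged from 1.38e-10 to 0.345 over the alternatives with a preset correlation.

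The lists of lipid synthesis and of interferon response genes were lower after 3Cl-HBA by a few percent, and both calls rest on a preset correlation. In the list of cholesterol and fatty acid synthesis, 4 of 24 members were above 0 and the median log2 fold change was -0.047 (camera adjusted p 0.0035, and adjusted p = 0.615 with an estimated correlation). Members with an unadjusted p under 0.05, named after their values were seen, included the cholesterol synthesis enzymes Fdps and Lss (log2 fold changes -0.13 and -0.27) and the stearoyl-CoA desaturase Scd (9.06 ± 1.53 and 6.82 ± 1 CPM, -0.42, SE 0.16). Fatty acid synthase Fasn had 203 ± 8.38 and 193 ± 3.78 CPM. In the interferon response list, 4 of 23 members were above 0 and the median was -0.063 (camera adjusted p 0.0035, and adjusted p = 0.464 with an estimated correlation). Ifit3, Ddx58, Irf9 and Ifi27, interferon-induced genes with an unadjusted p under 0.05, had log2 fold changes of -0.25, -0.21, -0.17 and -0.15. The mean log2 differences were -0.064 (95% interval -0.134 to 0.0062) and -0.090 (-0.155 to -0.026), with limma adjusted p of 0.521 and 0.179 over the 30 lists, and no member of either list passed, over all genes or adjusted over the list alone. The first call was lost without DMSO replicate 1 (adjusted p 0.148, range 3.77e-05 to 0.148 over the alternatives with a preset correlation) and the second without DMSO replicate 3 (0.063, range 0.00196 to 0.063). The lipid list had a median of -0.0800 without DMSO replicate 3, and the interferon list medians of -0.133, -0.0952 and -0.117 without DMSO replicate 1, DMSO replicate 2 and 3Cl-HBA replicate 3.

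The list of cell cycle genes was higher and that of adenylyl cyclases, phosphodiesterases and Gi signalling lower by a few percent, in the form of camera with a preset correlation only. Their estimated correlations, -0.018 and -0.0031, were below the preset 0.01, so both calls were lost with the fewer degrees of freedom of the other form (4 against 13901) and not with a higher correlation. In the list of DNA replication and mitosis, 23 of 29 members were above 0 and the median log2 fold change was 0.060 (camera adjusted p 0.0085, and adjusted p = 0.426 with an estimated correlation). The member with the lowest p, named after its value was seen, was the replication helicase subunit Mcm3, at 50.8 ± 1.08 and 57.6 ± 2.33 CPM, while the proliferation marker Mki67 had 172.5 ± 7.41 and 171 ± 15.7 CPM. In the list of adenylyl cyclase, phosphodiesterase and Gi signalling, 6 of 25 members were above 0 and the median was -0.073 (camera adjusted p 0.0155, and adjusted p = 0.426 with an estimated correlation). Its members with an unadjusted p under 0.05, named after their values were seen, were the phosphodiesterases, enzymes that degrade cyclic nucleotides, Pde4b (20.3 ± 0.389 and 16.9 ± 0.59 CPM, log2 fold change -0.27) and Pde2a (-0.16) and the anchoring protein Akap6 (-0.15), while the Gi subunit Gnai2 had 442 ± 12.2 and 449.5 ± 8.06 CPM. The mean log2 differences were 0.055 (95% interval 0.0022 to 0.108) and -0.085 (-0.146 to -0.023), with limma adjusted p of 0.428 and 0.179 over the 30 lists, and no member of either list passed, over all genes or adjusted over the list alone. The cell cycle call held in each alternative that kept the preset correlation (adjusted p 0.00481 to 0.0466), with a median of 0.0356 without DMSO replicate 1. The other was lost without DMSO replicate 1 (0.0585), DMSO replicate 3 (0.0959) or 3Cl-HBA replicate 1 (0.191, median -0.0427), with a range of 0.0141 to 0.191, and its median was -0.112 without 3Cl-HBA replicate 3.

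**Figure D3:**
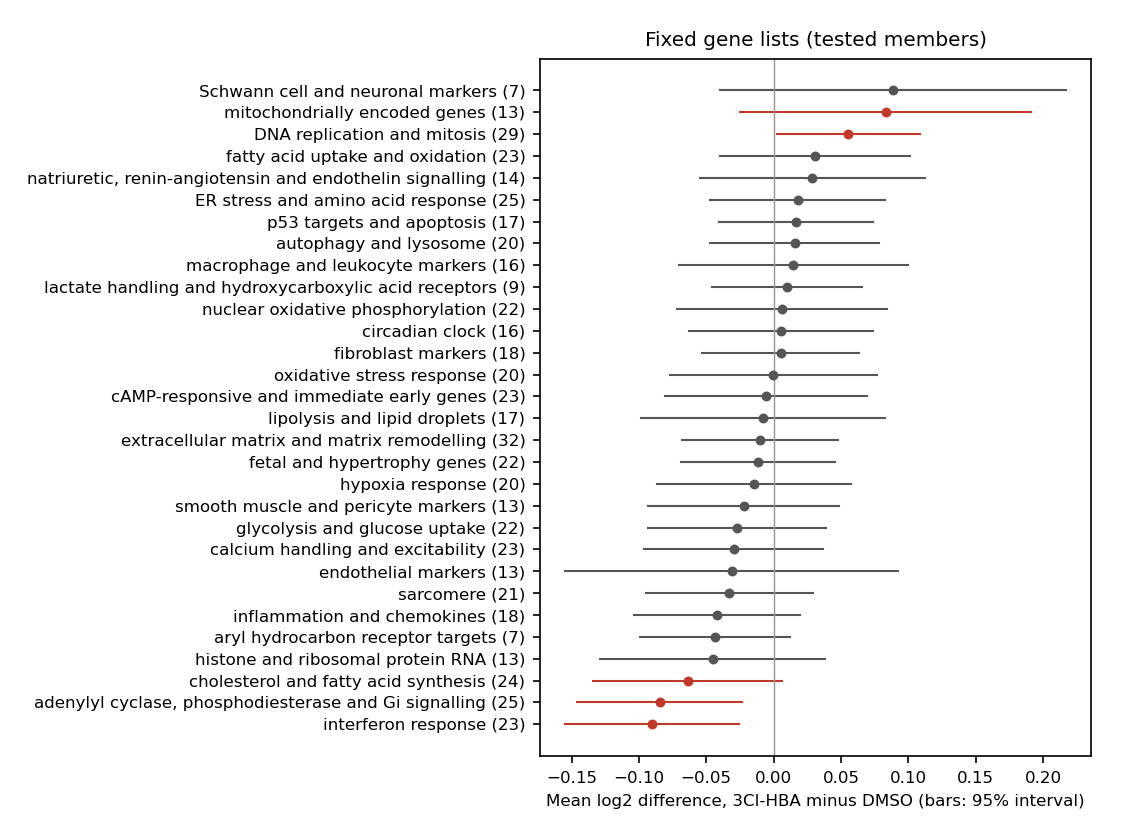
Mean log2 difference, 3Cl-HBA minus DMSO, of 30 gene lists (number of tested members in parentheses), with 95% intervals from limma as bars; red marks the 5 lists past camera with a preset correlation. The points lie between -0.090 and 0.089, and with an estimated correlation 0 lists passed.

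No remaining list of stress or signalling genes passed camera, the test for a shift against other genes. These were the lists of cAMP-responsive and immediate early genes, ER stress and amino acid response, oxidative stress response, hypoxia response, p53 targets and apoptosis, autophagy and lysosome, aryl hydrocarbon receptor targets, inflammation and chemokines, circadian clock, extracellular matrix and matrix remodelling, and histone and ribosomal protein RNA. They had 23, 25, 20, 20, 17, 20, 7, 18, 16, 32 and 13 tested members, and 0 members passed over all genes or adjusted over the list alone. The mean log2 differences lay between -0.045 for histone and ribosomal protein RNA (95% interval -0.129 to 0.038) and 0.018 for ER stress (-0.047 to 0.083). The immediate early gene Egr1 had 97 ± 7.68 CPM in DMSO and 107 ± 13.8 CPM after 3Cl-HBA, the chaperone Hspa5 964 ± 33.9 and 979.6 ± 13.6 CPM, the angiogenic factor Vegfa 589.8 ± 12.9 and 589.5 ± 21 CPM, the cell cycle inhibitor Cdkn1a 183 ± 4.7 and 189 ± 3.86 CPM, and Cyp1b1, a target of the aryl hydrocarbon receptor, 132 ± 6.09 and 136 ± 1.31 CPM. Fibronectin Fn1 had 6443 ± 236 and 6331 ± 363 CPM.

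Across the 30 lists tested, camera with a preset correlation called 5, and 0 with an estimated correlation. With the preset, splits of the libraries that mix the treatments called 0 to 5 lists each. fry, which asks whether a list's genes move on balance one way, called 0. Its mixed form, which asks whether they change in either direction, called 5, the lists of adenylyl cyclase, phosphodiesterase and Gi signalling (adjusted p 0.0037), interferon response (0.0115), p53 targets and apoptosis (0.0115), macrophage and leukocyte markers (0.0144) and cAMP-responsive and immediate early genes (0.0397). In the last of these, Junb had a log2 fold change of 0.14 and Pde4b, which the list shares with the adenylyl cyclase list, one of -0.27. Among macrophage markers, Cd68 had 0.11 and Cd163 -0.14; Junb and Cd163 were chosen after their values were seen. For the 25 lists that did not pass camera the adjusted p was 0.101 to 0.984, and the median, mean and camera direction differed in sign for the glycolysis, hypoxia, fibroblast, natriuretic, oxidative stress, lactate and circadian lists. With 1 library left out, other lists passed: sarcomere, downward, without DMSO replicate 1, DMSO replicate 2 or 3Cl-HBA replicate 3 (adjusted p 0.041, 0.0466 and 0.0226, range over the alternatives 0.0226 to 0.881), and fatty acid uptake and oxidation, upward, without DMSO replicate 3 (0.00919, range 0.00919 to 0.797). So did ER stress and amino acid response, upward, without 3Cl-HBA replicate 3 (0.0246, range 0.0246 to 0.809), and histone and ribosomal protein RNA, downward, without 3Cl-HBA replicate 1 (0.00291, range 0.00291 to 0.966). No enrichment of annotation terms could be tested on gene calls, as there were none, and camera over 3227 terms of 10 to 500 genes, a test chosen after the data were seen, called 0 terms (smallest adjusted p 0.138).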

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

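Removal of the length trend, the estimated inter-gene correlation as an alternative, other prior counts and camera over terms were chosen after the data were seen; the other settings were fixed before. The count of genes past the threshold, 0, stayed 0 with DESeq2, limma-voom, the other scalings, the stricter filter and removal of the length trend. It became 2 with no filter on low counts, and 0 to 8 with 1 library left out, of which 0 to 2 changed at least 2-fold; the cause was not tested. Genes at an unadjusted p under 0.05 numbered 405 with DESeq2, run without the filter on low counts, and 544 to 963 with 1 library left out. The 5 lists past camera became 0 with an estimated correlation and 3 to 7 with 1 library left out (3 without DMSO replicate 1). Acta1 and Myh6 changed sign with the length trend removed (-0.00039 and 0.0229). With 1 library left out, log2 fold changes ranged from -0.0589 to 0.0324 for Nppb, from -0.0232 to 0.0568 for Acta1 and from -0.0275 to 0.0272 for Myh6; each spans 0 and none was called. List medians changed sign in 53 of 450 combinations of list and setting, 38 of them with 1 library left out, and in 0 combinations for the 5 called lists. Libraries of the same number did not deviate together (correlations -0.069, -0.044 and -0.045), and no library correlated best with its own number. The labels do not say whether libraries of the same number share a cell preparation, and these correlations cannot settle it. With the replicate number as a block, 0 genes and 5 lists passed. The planned pseudocount was for a table without counts and was not run. With prior counts of 0.5 and 5 in the list tests, the same 5 lists passed camera with a preset correlation (adjusted p 0.00256 to 0.0153 and 0.00336 to 0.0158). With either prior count, 0 lists passed camera with an estimated correlation and 0 passed fry. The mixed form of fry called 5 lists with a prior count of 0.5 and 4 with a prior count of 5. Depth limits genes such as Hcar1, with 5 to 14 reads per library.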

Other observations

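Tests of Hcar1 levels, of terms, of counts at an unadjusted p and of lists in either direction over other splits were chosen after the results were seen. Removal of the length trend was added after the data were seen, with its bounds set before its own result, and the other tests were set before the results they measure. A few transcripts varied widely between libraries of one treatment, and are named here after their values were seen. Map3k7, a kinase of TGF-beta and inflammatory signalling, had 37, 33 and 32 reads in DMSO replicates 1 to 3 and 132, 23 and 164 reads in 3Cl-HBA replicates 1 to 3, and Zfp7 had 1, 0 and 1 against 20, 0 and 21. Both passed without 3Cl-HBA replicate 2 (log2 fold changes 1.99 and 4.58). Timp2, a metalloproteinase inhibitor, had 4978, 5470 and 6865 reads in DMSO and 7772, 8851 and 7499 after 3Cl-HBA, and passed without DMSO replicate 3 (log2 fold change 0.469). These are raw reads, and each treated library was deeper. Relative to library totals, Timp2 in DMSO replicate 3 lay above 3Cl-HBA replicates 2 and 3, so the groups overlap. The ribosomal protein gene Rps6 had only 1.1 ± 0.287 and 0.788 ± 0.204 CPM beside 861.5 ± 24.1 and 866 ± 44.3 CPM for Rpl4; reads shared with copies of Rps6 were not examined, so its level is uncertain.

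No gene passed between 3Cl-HBA and DMSO. The tables argue against a lack of power for many 2-fold changes at once, since 90% of such simulated changes were recovered. Responses of a few genes, which face a stricter cut-off after adjustment, were not simulated. An exchange of libraries between the groups that hid a response of 50 or more genes is also argued against. No other split of the 6 libraries called more than 8 genes. An explanation that stays open is that the cells held too little of the receptor: Hcar1 was at or below 0.954 CPM in each library, as that would need, although RNA levels do not measure the receptor protein. The 95% intervals lay inside 1.5-fold for 80.9% of genes (97.5% of those with at least 5 CPM), so smaller changes stay open, as do 1.5-fold changes of the other genes, and other times and proteins were not analysed here. The 10 splits of the 6 libraries are too few for a share under 0.05, and a real count of 0 is reached by any split, so the counts of 10 carry no information: 10 of 10 gave at least the real 0 genes (highest other 8), 10 of 10 at least the real 0 with a 2-fold change (highest other 2), 10 of 10 at least 0 terms past camera (highest other 40), and 5 of 10 at least 711 genes at an unadjusted p under 0.05 (highest other 966).

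The split with 8 genes and 40 terms set DMSO replicate 1 with 3Cl-HBA replicates 2 and 3, and a split with 2 genes and 39 terms set DMSO replicates 1 and 2 with 3Cl-HBA replicate 2. Whether these counts exceed chance was not tested. Their log2 fold changes had Spearman correlations with gene length of -0.3 and -0.292 across genes, which are not independent replicates, against -0.187 for the real split; the splits were not refitted with the length trend removed. The log2 level changed per doubling of gene length by 0.03, 0.0028 and -0.0083 in DMSO replicates 1 to 3 and by -0.0394, 0.0123 and 0.0027 in 3Cl-HBA replicates 1 to 3.

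Small shifts of 5 lists past camera with a preset correlation are the second pattern. A gene length trend is argued against as their whole cause, since 5 of 5 stayed past the threshold with it removed. Chance stays open for all 5, and a spread shared by genes of a list for the mitochondrial, interferon and cholesterol lists, with estimated correlations of 0.275, 0.047 and 0.085 against the preset 0.01; those of the cell cycle and adenylyl cyclase lists were lower than the preset (-0.018 and -0.0031). With estimated correlations, a form of camera with 4 degrees of freedom against 13901, 0 passed. With the preset, 3 of the 10 splits, the real one among them, gave at least 5 lists (real 5, highest other 5). These splits are too few for a share under 0.05. The other splits, which mix the treatments, called 0 to 5 lists each. Only that of DMSO replicates 1 and 2 with 3Cl-HBA replicate 3 called 0. For lists changing in either direction by fry, 1 of the 10 splits, the real one, gave 5 lists (highest other 2), which the 10 splits are again too few to judge. A response to 3Cl-HBA is a hypothesis that these 6 libraries leave open.

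Hba-a1 had the largest upward log2 fold change of the 16 genes named by the rule fixed in advance, and more RNA of red blood cells after 3Cl-HBA was tested as an explanation. The other erythroid genes of at least 1 CPM had a median log2 fold change of 0.0077 (Hba-a2 0.021 with a 95% interval of -0.232 to 0.274, Hbb 0.0077, Slc4a1 -0.063), which argues against it as the cause. Hba-a2 had 11.9 ± 0.457 CPM in DMSO and 12.1 ± 0.899 CPM after 3Cl-HBA, and Hbb 7.53 ± 0.785 and 7.6 ± 1.34 CPM; of the erythroid list only Hba-a1 passed adjusted over the list alone (0.00098). Chance, an effect of 3Cl-HBA and reads shared between the near copies Hba-a1 and Hba-a2, which was not tested, stay open.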
